A study of Mus musculus with 6 samples.

How the data were processed

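The study measured gene expression in cultured mouse embryonic fibroblasts with Affymetrix gene-level arrays. Per the labels, 3 arrays came from cells with the control hairpin shSCR and 3 from cells with the hairpin shARF. Total RNA was extracted from trypsinised cells and amplified to biotinylated cDNA, per the labels' protocols. The deposited values are intensities on a linear scale, one per probeset and array. Per the submitters' processing notes and the series design text, the authors normalized the arrays with RMA (robust multi-array average, which corrects the background, quantile normalizes and summarises probes) in Affymetrix Expression Console, using core probesets. No version is given in the sources used here. The design text also describes leaving out control probesets and probesets absent on 12 arrays, with presence set at the mean of the negative controls plus 2 SD, and a test with SAM (significance analysis of microarrays). The 6 arrays above are those analysed here. RMA gives log2 values, and the deposited intensities, from 3.14 to 12717.5, lie on a linear scale, so they were turned to log2 here. Quantile normalization gives all arrays nearly one distribution, so a change common to most genes would not show, and RMA background correction makes folds of dim genes smaller. Signal medians per array were 41.97 to 42.86, and 0 values were missing.

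Probesets were named from the platform annotation given with the data. Of 26851 probesets, 21056 (78.4%) carried 1 gene symbol, 1450 several and 4345 none. Genes with several symbols on a probeset were not named. The symbols stood for 19288 genes, and 0 symbols changed when matched to the RefSeq gene table of assembly GRCm38.p6, which was used for names and for the chromosome of each gene. No build is given for the array, so no coordinates are printed. For 396 probesets the 6 values equalled those of an earlier probeset. Depth has no counterpart on an array, and the number of arrays limits the precision.

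A probeset was tested if its value exceeded the detection level on at least 3 of the 6 arrays. The detection level was the 25th percentile of each array's values, 14.1 to 14.9 in signal, the choice planned for a table with no negative control probesets named; the submitters' rule was not used here. This left 20310 probesets and 15145 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), and p-values were adjusted with the Benjamini-Hochberg method over all tested probesets, with a threshold of 0.05. Each gene was represented by its probeset with the highest mean. Of 815 genes with several tested probesets, 0 had probesets called in opposite directions and 34 had some probesets called and others not. At probeset level 737 changed, 331 higher and 406 lower. The median SD between replicates was 0.103 and the median SE of a difference 0.0815, both on the log2 scale. The prior had 3.28 degrees of freedom. A gene above the detection level on 0 arrays of a group has only a bound there: the mean of the other group is set against the detection level of each array, or the array's own value where higher, and the fold is given as at least that ratio. Levels are means ± SD of the linear signal, and folds come from the log2 means. Genes not above the detection level on 3 or more arrays and genes with no single-gene probeset were not analysed here.

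The test design, the gene lists, the cell type markers and the rule for naming genes were fixed before the data were examined. The rule took Cdkn2a, Cdkn2b, Trp53, Mdm2, Hras and Nras in any case. It then took the 12 largest rises and 12 largest falls among genes that passed the test, whose arrays did not overlap between groups, leaving out olfactory and vomeronasal receptors, small RNAs, predicted genes and pseudogenes. It also took up to 4 measured members of each list with the smallest p, and Isg15, Stat2, Irf7, Irf9, Ifnb1 and Usp18 always. Some genes that the rule names are not reported here. Other called members of the lists and the cell type markers named in the results were chosen after their values were seen. There were 20 gene lists, on interferon-stimulated genes, interferons with their receptors and early signalling, interferon-induced GTPases, MHC class I antigen presentation, inflammatory cytokines, p53 targets, G1/S, G2/M, ribosome biogenesis, MYC targets, RAS and ERK output, extracellular matrix, matrix proteases, TGF-beta responses with contractile genes, apoptosis, DNA repair, unfolded protein and amino acid stress, glycolysis and hypoxia, cholesterol biosynthesis, and the NRF2 response. With the markers of fibroblasts, macrophages, lymphocytes, endothelium, epithelium, neural cells, muscle, adipocytes, and cartilage and bone there were 29 lists. The 27 with at least 5 measured members were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 27), and 3 were called. With a correlation estimated from the data 0 were called, and 2 had an unadjusted p under 0.05; fry called 3.

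The alternatives were a SAM statistic written for this work with all 20 arrangements of the labels and a false discovery rate of 0.05, eBayes with trend and robust settings, no filter, a filter at the 50th percentile, quantile normalization, median centring, array weights, the mean of a gene's probesets, the replicate number as a block, leaving out each array in turn with the full set of tested probesets, and for lists an estimated correlation and fry. The design text names SAM without the settings that fix its calls, so limma was the main test. The procedure was tested on simulated data with 200 changed genes among the 20310 probesets of the shARF against shSCR comparison. limma recovered 59.7%, 95.5% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, and SAM 59.7%, 98.5% and 100%. False calls made up 6.63% of limma's calls and 7.53% of SAM's. The list test called the shifted list and 0 of 40 unshifted lists. The spread of each simulated gene was drawn from limma's own fitted prior. The rates of recovery and of false calls therefore hold under limma's model and may differ for the real genes. The simulated genes varied independently, so the simulation does not show how the list test behaves where members vary together across arrays. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.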

Results

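The data were 6 Affymetrix gene-level arrays of cultured mouse embryonic fibroblasts, in 2 groups of 3 labelled biological replicates. The control group carried a hairpin construct labelled shSCR, and the other group carried a hairpin labelled shARF. A short hairpin RNA is a vector-encoded transcript that lowers the messenger RNA it matches. ARF is a tumour suppressor protein made from the Cdkn2a locus, best known for holding back MDM2 and thereby stabilising p53. The series title names the cells dp53R, and the sample titles carry the word Ras. The design asks which transcripts differ when ARF is lowered in these cells. Each array gave a normalized linear signal for 26851 probesets, with medians of 42.3 to 42.5 in shSCR and 41.97 to 42.86 in shARF. The number of arrays, 3 per group, limits the precision. The labels call the replicates biological but do not say whether they came from separate cultures or animals. The p-values therefore measure the spread between these samples, which may not reflect that between separate cultures or animals.

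The hairpin's target was lower in every shARF array. Cdkn2a (probeset 10514340) gave a signal of 530 ± 12.3 (SD, n = 3) in shSCR and 285 ± 30.7 in shARF. It fell by 0.90 ± 0.086 (SE) on the log2 scale, a 1.87-fold drop (limma, adjusted p = 0.00459). The lowest shSCR array gave 516 and the highest shARF array 315.4. The call held without any 1 array, with adjusted p between 0.00944 and 0.0282 in limma. This probeset is annotated to the gene Cdkn2a. The locus also encodes p16Ink4a, a cell cycle inhibitor that shares exons with ARF, so the probeset may read both. The neighbouring inhibitor gene Cdkn2b measured 645 ± 34.8 in shSCR and 838 ± 67.4 in shARF and did not pass the test (limma, adjusted p = 0.0521). Mdm2, which encodes the ubiquitin ligase of p53, differed by -0.20 ± 0.055 (limma, adjusted p = 0.11), and Nras by 0.03 ± 0.071 (limma, adjusted p = 0.847). Neither passed. Trp53 and Hras were not analysed here.

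The largest changes in shARF cells were rises of genes of the interferon response. Among 15145 genes tested, 607 changed at an adjusted p under 0.05 in limma, 246 higher and 361 lower in shARF, which is 4.01% of the genes. Of these, 57 changed at least 2-fold, 46 of them higher and 11 lower. Of the 46, 27 stood on one of the lists of interferon-stimulated genes, interferon-induced GTPases or MHC class I antigen presentation, which hold 60 of the tested genes. The 12 largest rises under the naming rule were those of Rtp4, Oasl2, Ifi27l2a, Ifit3, Ifit1, Usp18, Ifit3b, Cxcl10, Gbp7, Bst2, Xaf1 and Ifih1, from 9.24-fold for Rtp4 to 3.47-fold for Ifih1. The groups did not overlap for 4332 genes, or 28.6%, where chance gives 10%. Array values correlated at 0.996 to 0.997 within a group and at 0.992 to 0.994 between groups over the tested probesets, and these are correlations across probesets, which are not independent replicates. The count of 607 was lower with fewer arrays: it was 165, 306 and 150 without shSCR replicate 1, 2 and 3, and 253, 330 and 244 without shARF replicate 1, 2 and 3. The count of 57 was 37 without shSCR replicate 1.

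Interferon-stimulated genes rose together. Of the 42 measured members, 35 rose and 0 fell, 7 did not pass, and all 42 differences were positive, with a median of 1.00 on the log2 scale (range 0.06 to 3.21). Adjusted over the list alone, 41 members rose. SAM called 40 higher and 0 lower, and at an unadjusted p under 0.05 limma gave 41 higher and 0 lower. This list was chosen in the knowledge that the study concerns interferon signalling, so it is not independent evidence of its direction. Ifit3, of the IFIT family of antiviral proteins, rose from 66.8 ± 16.9 (SD, n = 3) to 408 ± 23.4, a log2 change of 2.64 ± 0.171 (SE; limma, adjusted p = 0.00154). Ifit1, which encodes an RNA-binding member of that family, rose from 62.3 ± 17.4 to 362 ± 75.3, and Oasl2, of the oligoadenylate synthetase family, from 43.1 ± 18.2 to 313 ± 35.6. Ifih1, the cytosolic sensor of double-stranded RNA MDA5, rose 3.47-fold. The members that did not pass were Ifi35, Oas1b, Oas3, Oasl1, Trim30a, Epsti1 and Ifi203, with differences of 0.06 for Oas3 to 0.92 for Oasl1.

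**Figure D1:**
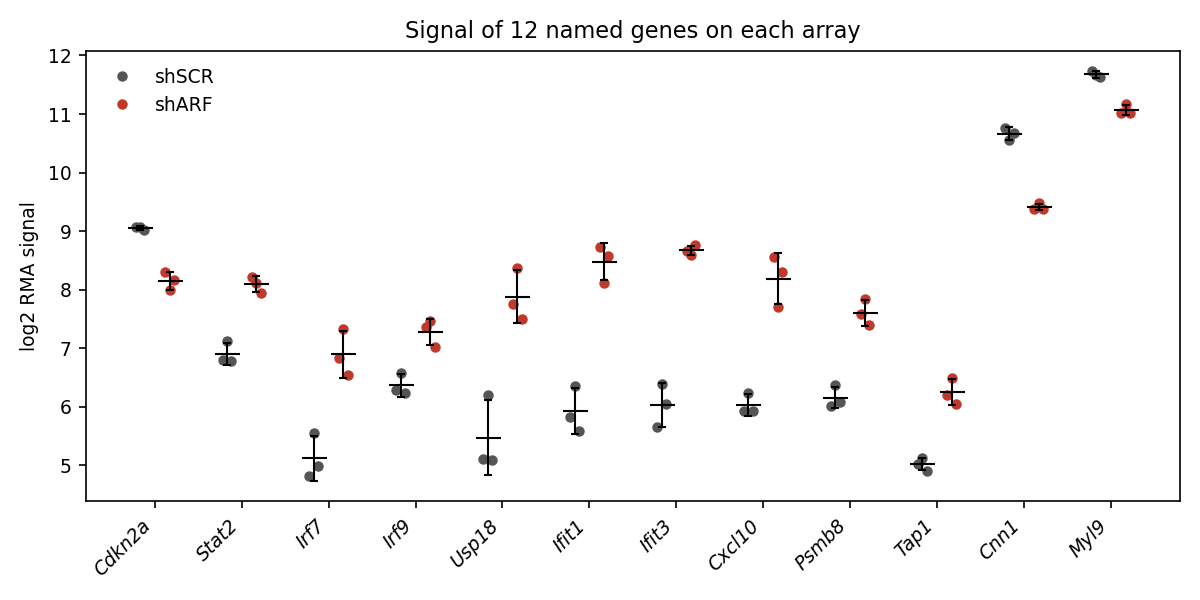
Signal (log2 RMA signal, vertical axis) of 12 named genes on each array; grey points are the 3 shSCR arrays, red points the 3 shARF arrays, and bars show the mean and SD. Cdkn2a, Cnn1 and Myl9 lie lower in all 3 shARF arrays than in any shSCR array, and the other 9 genes lie higher.

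The transcription factors that carry the interferon signal rose as well. Stat2 rose from 121 ± 16.4 (SD, n = 3) to 274 ± 26.2, a log2 change of 1.19 ± 0.114 (SE; limma, adjusted p = 0.00459). Irf7, which amplifies interferon production, rose from 35.7 ± 10.0 to 122 ± 34.5, and Irf9, the DNA-binding partner of STAT2, from 83.1 ± 11.4 to 157 ± 23.7. Usp18, a negative regulator of the interferon receptor, rose from 47.6 ± 22.8 to 244 ± 78.9. Isg15 was not analysed here. The list shifted as a whole in limma's camera test with a preset correlation (adjusted p = 2.02e-42), and the call was lost with an estimated correlation (adjusted p = 0.403 with an estimated correlation, in a range of 3.70e-53 to 0.403 over all alternatives). The fry test of a shift in one direction called it (adjusted p = 0.00949).

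Support for single interferon genes was uneven across arrays. In both groups the replicate 2 array held the highest value for most of the list: 35 of 42 members in shSCR and 26 of 42 in shARF. The calls of 14 of the 35 genes held without any 1 array, among them Ifit1, Ifit3, Oasl2, Ifih1, Stat2, Xaf1 and Zbp1. The number called was 16, 32 and 17 without shSCR replicate 1, 2 and 3, and 23, 25 and 27 without shARF replicate 1, 2 and 3. Usp18 and Irf7 lost their calls without shSCR replicate 1 or 3 (highest adjusted p in limma 0.0668 and 0.0676), and Rtp4 without shSCR replicate 3 (0.0516). Irf9 lost its call without 4 of the arrays, and Bst2 and Ifi27l2a each without 5. Without both replicate 2 arrays, a setting chosen after seeing the data, 25 members were called. In these shARF arrays a few markers of other cell types were also higher, among them the neurofilament gene Nefl (1.26 ± 0.135, log2), the simple-epithelium keratin gene Krt18 (0.93 ± 0.176) and the leukocyte surface gene Cd53 (0.66 ± 0.132).

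Most measured genes on the list of receptors and early signalling of this response did not pass. The sensor gene Ifih1 and the factors Stat2, Irf7 and Irf9 were counted with the interferon-stimulated genes, where they rose. The list of interferons, their receptors and early signalling had 19 measured genes, none of them an interferon gene. Of the 19, 1 rose, 1 fell and 17 did not pass. Adjusted over the list alone 1 rose and 2 fell. SAM called 1 higher and 2 lower, and at an unadjusted p under 0.05 limma gave 1 higher and 4 lower. Irf1, an interferon-induced transcription factor, rose from 128 ± 5.8 (SD, n = 3) to 173 ± 10.2, and Ifngr1, a chain of the interferon gamma receptor, fell from 227 ± 6.61 to 155 ± 18.1. Irf1 lost its call without 5 of the 6 arrays and Ifngr1 without 4. Ifnar1, a chain of the type I interferon receptor, differed by -0.28 ± 0.061 and did not pass (limma, adjusted p = 0.0572). The interferon beta gene Ifnb1 lay below the detection level on all 6 arrays, at 7.77 ± 0.391 in shSCR and 8.38 ± 1.27 in shARF, so no fold is given. The list median was -0.05 (camera, adjusted p = 0.662).

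Interferon-induced GTPases and 7 of 14 measured antigen presentation genes rose with the interferon-stimulated genes. All 4 measured GTPases and guanylate-binding proteins rose, over all genes and adjusted over the list alone: Gbp7 3.86-fold, Irgm1 3.16-fold, Gbp3 2.75-fold and Iigp1 at least 2.37-fold. Iigp1 was above the detection level on 0 shSCR arrays, and its bound sets the shARF mean against that level. Irgm1 lost its call without shSCR replicate 1 (limma, adjusted p = 0.0516). Of 14 measured genes of MHC class I antigen presentation, 7 rose and 0 fell, 9 and 0 adjusted over the list alone, with a median log2 difference of 0.31; SAM called 9 higher and 0 lower, and at an unadjusted p under 0.05 limma gave 12 higher and 0 lower. The immunoproteasome subunit gene Psmb8 rose from 71.7 ± 9.43 (SD, n = 3) to 196 ± 30.5, and the peptide transporter gene Tap1 from 32.5 ± 2.41 to 76.7 ± 11.9. B2m, the light chain of class I molecules, rose 1.24-fold from 3498 ± 136 to 4330 ± 43.9, a call lost on leaving out any 1 of the 6 arrays. Psmb8, Tap1 and Erap1 kept theirs in all 6 cases. The list was called by camera (adjusted p = 2.01e-11), not with an estimated correlation (adjusted p = 0.479, in a range of 2.36e-13 to 0.479 over all alternatives), and by fry (adjusted p = 0.0179). Probes of Ifit3 and Ifit3b, of Gbp3 and Gbp7, and of Oas1a and H2-Q4 can read near-identical family members, so single values for these genes are uncertain.

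**Figure D2:**
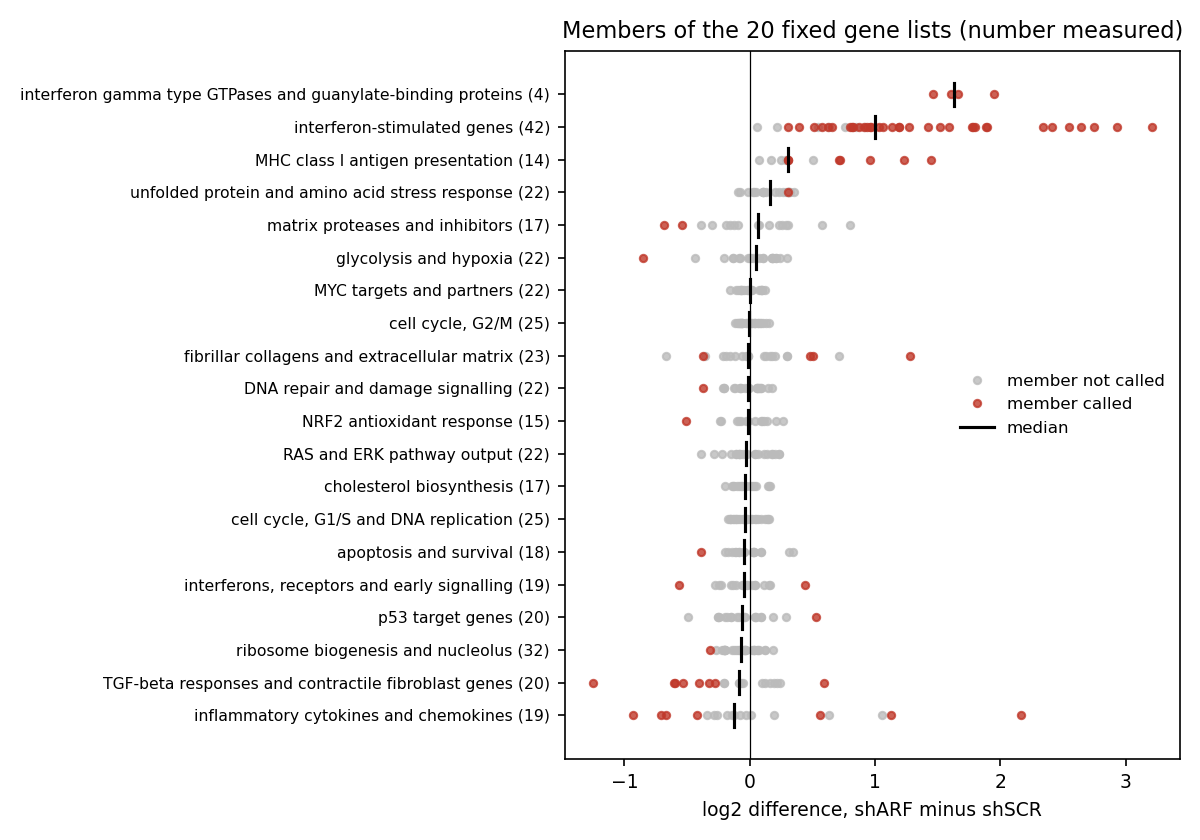
Log2 difference, shARF minus shSCR (horizontal axis), of each measured member of the 20 gene lists; red points passed limma's test over all genes, grey points did not, and black bars mark the list median. The median lies at 1.63 for the GTPases, 1.00 for the interferon-stimulated genes and 0.31 for antigen presentation, and between -0.13 and 0.17 for the other lists.

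Cytokine and chemokine genes moved both ways. Of 19 measured, 3 rose, 4 fell and 12 did not pass; adjusted over the list alone, 4 rose and 6 fell. Cxcl10, an interferon-inducible chemokine, rose from 65.6 ± 8.66 (SD, n = 3) to 300.3 ± 84.5, a log2 change of 2.16 ± 0.209 (SE; limma, adjusted p = 0.00459), and Ccl8 and Ccl20 rose 2.19-fold and 1.47-fold. The neutrophil chemokine genes Cxcl5 and Cxcl1 fell 1.63-fold and 1.59-fold. Ptgs2, which encodes cyclooxygenase 2, fell from 3156 ± 224 to 2349 ± 45.1, and Tslp fell from 195 ± 41.1 to 102 ± 18.1. The list median was -0.13 and its mean 0.08, so the signs differ, and camera did not call it (adjusted p = 0.662). Cxcl10, Cxcl5 and Cxcl1 kept their calls without any 1 array, and each of Ccl8, Ccl20, Ptgs2 and Tslp lost its call without 5 of the 6.

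Some contractile genes fell, while their list as a whole was not called. Of 20 measured genes of TGF-beta responses and the contractile apparatus, 7 fell, 1 rose and 12 did not pass, and adjusted over the list alone 9 fell and 1 rose. Cnn1, the smooth muscle actin-binding protein calponin, fell from 1628 ± 123 (SD, n = 3) to 682 ± 24.9, a log2 change of -1.25 ± 0.074 (SE; limma, adjusted p = 0.00121). Myl9, a regulatory myosin light chain, fell from 3270 ± 120 to 2154 ± 134. Actg2, Ltbp2, Tagln, Tpm2 and Acta2 fell by 0.59, 0.53, 0.41, 0.32 and 0.28 on the log2 scale, and Tgfbi rose by 0.59. The growth factor genes Tgfb1, Tgfb2 and Tgfb3 differed by -0.08, 0.24 and 0.20 and did not pass. The list median was -0.08 (camera, adjusted p = 0.107). Cnn1 and Myl9 kept their calls without any 1 array, and the number of members called was 3, 5 and 2 without shSCR replicate 1, 2 and 3 and 3, 6 and 4 without shARF replicate 1, 2 and 3.

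Matrix genes changed without a common direction. Of 23 measured genes of collagens and extracellular matrix, 3 rose and 1 fell, and 5 rose and 3 fell adjusted over the list alone. Lum, a collagen-binding proteoglycan, rose from 101 ± 18.6 (SD, n = 3) to 249 ± 71.7, while Eln and Postn rose 1.42-fold and 1.39-fold and Fbln2 fell 1.29-fold. Postn lost its call on leaving out any 1 of the 6 arrays, Lum and Fbln2 each without 5 of the 6, and Eln without shSCR replicate 1 or 3. Of 17 measured matrix proteases and inhibitors, 2 fell and 0 rose (SAM called 2 lower and 2 higher, and 3 were lower and 5 higher at an unadjusted p under 0.05 in limma), and 3 fell and 3 rose adjusted over the list alone. Timp3, an inhibitor of matrix proteases, fell from 1405 ± 105 to 964 ± 37.0, and Adamts12 fell 1.61-fold, a call lost without shSCR replicate 1 or 3 (highest adjusted p in limma 0.0614). Camera called neither list (adjusted p = 0.245 and 0.815).

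The largest falls outside these lists were of genes with varied functions. Ppbp, which encodes a platelet chemokine, fell from 193 ± 31.6 (SD, n = 3) to 57.7 ± 4.3, a log2 change of -1.73 ± 0.128 (SE; limma, adjusted p = 0.00225). Cck, the gene of the peptide hormone cholecystokinin, fell 2.70-fold, and U90926 fell 3.15-fold. Sfrp2, a secreted WNT modulator, fell from 446 ± 34.1 to 223 ± 18.8. Ptchd4, Akr1c18, Gjb2, Slc1a6, Wnk3, Fsd1 and Gabrb1 fell 2.32-fold, 2.30-fold, 2.17-fold, 2.11-fold, 2.08-fold, 2.04-fold and 1.98-fold. Of these, Ptchd4 lost its call without shSCR replicate 1, and Gjb2 and Slc1a6 without shSCR replicate 3 (limma, adjusted p = 0.0511, 0.0577 and 0.0546).

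**Figure D3:**
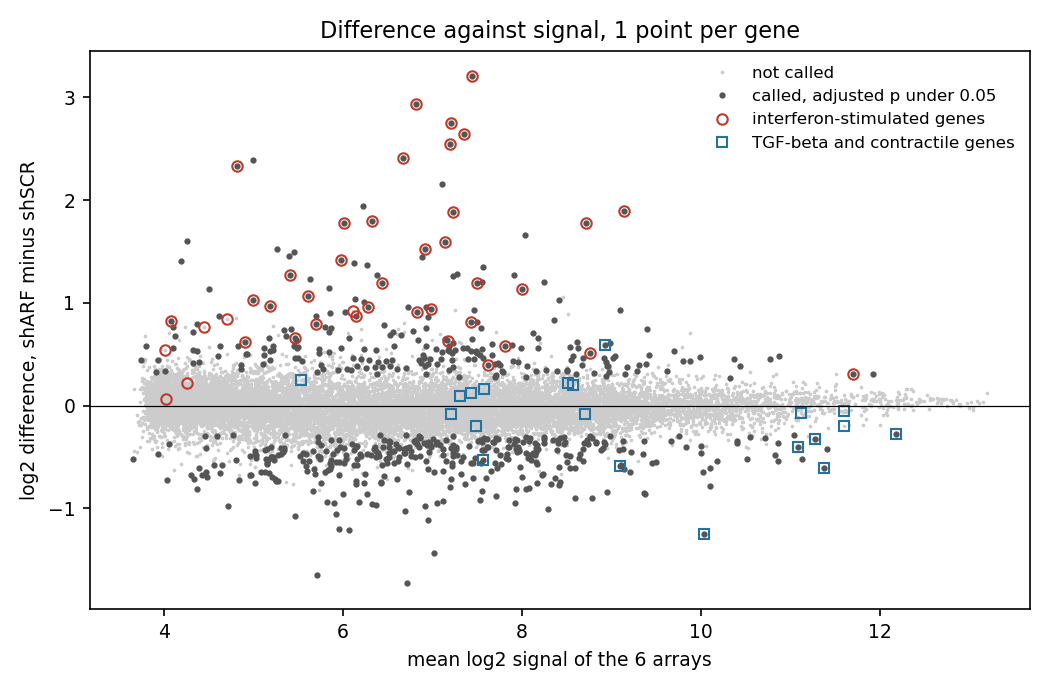
Log2 difference, shARF minus shSCR (vertical axis), against the mean log2 signal of the 6 arrays (horizontal axis), with 1 point per tested gene; dark points are the 607 genes that passed limma's test, red circles the 42 interferon-stimulated genes and blue squares the 20 TGF-beta and contractile genes. The interferon-stimulated genes all lie above 0 and reach 3.21, and the lowest contractile gene, Cnn1, lies at -1.25.

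Genes of p53 output, proliferation and growth showed few changes. The p53 status of the cells is not given in the sources used here, which limits what the p53 targets can show. The p53 targets Cdkn1a, Bax and Gdf15, on the fixed list, had no single-gene probeset and were not measured. Of 20 measured p53 target genes, 1 rose (Eda2r, 1.44-fold) and 0 fell. SAM called 1 higher and 1 lower, and at an unadjusted p under 0.05 limma gave 3 higher and 4 lower. Adjusted over the list alone the counts were 1 and 1. Zmat3, a p53 target that binds RNA, differed by -0.49 ± 0.111 and did not pass (limma, adjusted p = 0.0629). Neither 25 genes of G1/S and DNA replication nor 25 genes of G2/M held any that passed limma's test, over all genes or adjusted over the list alone, and SAM called 0 in each. At an unadjusted p under 0.05, limma gave 1 higher and 3 lower in the first list and 0 in the other. Of 32 genes of ribosome biogenesis and the nucleolus, where ARF resides, 1 fell (Rrp12, 1.25-fold), in both adjustments and in SAM; at an unadjusted p under 0.05 limma gave 1 higher and 8 lower, and 10 of the 32 differences were positive. Without shARF replicate 2 camera called this list (adjusted p = 0.0459, in a range of 0.0459 to 0.934 over all alternatives). Among 22 MYC targets and partners 0 passed limma's test or SAM, and 0 had an unadjusted p under 0.05. Among 22 genes of RAS and ERK output 0 passed limma's test in either adjustment, SAM called 1 lower, and 4 were higher and 4 lower at an unadjusted p under 0.05. The medians of these 6 lists lay between -0.07 and 0.00 on the log2 scale, and camera called none of them with all 6 arrays (adjusted p from 0.147 to 0.855). The calls of Eda2r and Rrp12 were lost without 5 and 6 of the arrays in turn.

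Stress response genes shifted slightly upward in camera, and the groups overlapped. Of 22 measured genes of the unfolded protein and amino acid stress response, 19 differences were positive, and 1 gene, the growth inhibitor Ddit4, rose 1.24-fold in both adjustments, a call lost on leaving out any 1 of the 6 arrays. The list medians per array, relative to the shSCR mean, were -0.095, 0.131 and -0.043 on shSCR replicates 1, 2 and 3 and 0.198, 0.173 and 0.128 on shARF replicates 1, 2 and 3. The median difference was 0.17 on the log2 scale, and camera called the list (adjusted p = 7.11e-04), a call lost with an estimated correlation (adjusted p = 0.934, in a range of 6.40e-08 to 0.934 over all alternatives) and in fry (adjusted p = 0.252). Among 22 genes of glycolysis and hypoxia 1 fell, and 2 fell and 2 rose adjusted over the list alone. The falling gene, Adm, encodes the vasodilator peptide adrenomedullin and went from 889 ± 23.5 (SD, n = 3) to 494 ± 54.6. Single genes also fell, in both adjustments, among 18 genes of apoptosis and survival (Birc3, 1.31-fold), 22 of DNA repair (Lig4, 1.29-fold) and 15 of the NRF2 antioxidant response (Gsta4, 1.42-fold), and these calls were lost without 5, 6 and 5 of the arrays. Of 17 cholesterol biosynthesis genes 0 passed limma's test in either adjustment or SAM, and 0 had an unadjusted p under 0.05. Camera called none of these 5 lists (adjusted p from 0.592 to 0.978).

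Markers of cell types were mostly level between the groups. None of 12 fibroblast and mesenchymal markers passed limma's test in either adjustment, with a median of -0.08; SAM called 1 lower, and 1 was higher and 4 lower at an unadjusted p under 0.05. Of 8 epithelial markers Krt18 rose from 129 ± 11.03 (SD, n = 3) to 250.2 ± 63.8, and its partner keratin gene Krt8 differed by 0.74 ± 0.164 without passing (limma, adjusted p = 0.0583). Of 11 neural markers Nefl rose from 97.0 ± 8.89 to 234 ± 40.2. Of 10 muscle markers 2 rose, the cardiac troponin gene Tnnt2 1.88-fold and the acetylcholine receptor gene Chrna1 1.499-fold, and of 7 macrophage markers 1 rose, Cd53 1.58-fold. Adjusted over the list alone, 3 epithelial, 3 neural, 2 muscle and 2 macrophage markers rose and 1, 1, 0 and 2 fell. Among 8 endothelial markers 0 passed over all genes and 1 rose and 1 fell adjusted over the list alone, where SAM called 1 lower, and 1 was higher and 1 lower at an unadjusted p under 0.05. None of 3 lymphocyte, 5 adipocyte and 7 cartilage and bone markers passed limma's test in either adjustment or SAM, and 1, 0 and 0 had an unadjusted p under 0.05. Camera called none of the 8 cell type lists it could test (adjusted p from 0.108 to 0.813), while fry called the muscle list (adjusted p = 0.00949, in a range of 0.00949 to 0.479 over all alternatives). Without shARF replicate 2 camera called the epithelial and neural lists (adjusted p = 0.0459 and 0.0347, in ranges of 0.0459 to 0.479 and 0.0347 to 0.479 over all alternatives). Only the call of Nefl held without any 1 array.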

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

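Leaving out both replicate 2 arrays was chosen after seeing the data; the other settings were planned. The direction of Cdkn2a and its call held under every alternative run, and so did the sign of all 607 called genes wherever they were tested. The count of 607 changed genes became 1079 with SAM (all 607 shared), 1281 with trend and robust settings (594 shared), 372 with no low-value filter, 996 with the stricter filter, and 150 (without shSCR replicate 3) to 330 (without shARF replicate 2) when 1 array was left out. It was 137 without both arrays of replicate 2, of which 59.1% were higher, against 40.5%. It stayed between 583 and 658 with quantile normalization, median centring, array weights and the mean of probesets. The filters change both how many genes share the adjustment and which genes set limma's prior, and these effects were not separated. For the other settings the cause was not tested beyond the smaller number of arrays. The count of genes changed at least 2-fold ranged from 37 (without shSCR replicate 1) to 61 (without shSCR replicate 2), and was 62 without both replicate 2 arrays. The number of lists called, 3, became 5 with no filter, 0 with an estimated correlation, and 3 to 7 with 1 array left out, the 7 without shARF replicate 2. The median of the interferon-stimulated genes was 1.00 with an estimated correlation as before, but its call was lost (adjusted p = 0.403, against 3.70e-53 to 0.00949 in the other alternatives). The TGF-beta and contractile list, not called in the planned test, was called with trend and robust settings (adjusted p = 0.00911), no filter (0.0321), without shSCR replicate 2 (0.0341), without shARF replicate 2 (0.0459) and without both replicate 2 arrays (0.0304), in a range of 0.00911 to 0.934. Of 113 called genes that were followed, 52 kept their call whichever 1 array was left out.

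The labels give the groups the same replicate numbers. Deviations of same-numbered arrays from their group means correlated at 0.078, 0.052 and 0.001 over all tested probesets, and shSCR replicate 3 correlated best with shARF replicate 2 (0.094), so by this measure the samples share only a number. Over the interferon-stimulated genes the same-numbered arrays correlated at 0.047, 0.447 and 0.551 and the others at -0.54 to 0.349, so shared variation of replicates 2 and 3 within that list stays open. With the number as a replicate block, 336 genes were called, 294 of them among the 607. Signal over background limits what can be read for dim genes: the detection level lay at 14.1 to 14.9 in signal against array medians of 41.97 to 42.86.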

Other observations

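The tests of explanations below were chosen only after the result was seen, except the test of BMP targets, and the genes of the next paragraphs were named after their values were seen.

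Of the genes changed at least 2-fold in shARF cells, 25 stood on none of the fixed lists, 15 higher and 10 lower. Several of the 15 are known interferon-inducible genes. Rnf213, a large ubiquitin ligase, rose from 121 ± 24.1 (SD, n = 3) to 304.1 ± 26.4, a log2 change of 1.35 ± 0.141 (SE; limma, adjusted p = 0.0062). Slfn2 rose 2.87-fold, Phf11d 2.82-fold, Trim12c 2.05-fold and the RNA helicase gene Ddx60 at least 2.11-fold, since its signal lay below the detection level on the shSCR arrays. Other rises were those of the lipocalin gene Apod (2.61-fold), Itgbl1 (2.42-fold), Tcim (2.42-fold), Serinc2 (2.30-fold), the matrix gene Dpt from 202 ± 20.2 to 468 ± 82.4, the ectonucleotidase gene Entpd1 (2.04-fold) and the heparan sulfatase gene Sulf2 (2.01-fold). Ly6g rose 2.58-fold. Of the genes named here, Phf11d lost its call without shSCR replicate 1 or 3 and Ly6g without 5 of the 6 arrays, and the others kept theirs whichever 1 array was left out.

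The inhibitors of differentiation Id1, Id2 and Id3, which block basic helix-loop-helix factors, fell together. Id1 went from 605 ± 24.1 (SD, n = 3) to 324 ± 6.16, a log2 change of -0.90 ± 0.059 (SE; limma, adjusted p = 0.00154). Id2 fell 1.70-fold and Id3 1.52-fold, and the transcription factor gene Atoh8 fell from 82.8 ± 0.604 to 43.2 ± 6.18. Bmp2, the gene of a secreted growth factor, rose from 39.3 ± 8.3 to 87.05 ± 19.6. Id1, Id2 and Atoh8 kept their calls without any 1 array, Id3 lost its call on leaving out any 1 of the 3 shSCR arrays, and Bmp2 without 4 of the 6 arrays.

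Lower output of BMP signalling was a hypothesis for the fall of the Id genes, which are BMP targets. It predicted that most of 10 other BMP target genes, listed before their values were seen, would be called lower. In limma and in SAM 1 was called lower, Id4 (1.498-fold, a call lost on leaving out any 1 of the 6 arrays), and 0 higher. The prediction therefore failed, which argues only against a fall large enough for most of these genes to be called. In the simulated data limma recovered 59.7% of genes changed by 0.5 on the log2 scale, so smaller falls can be missed. The differences of Msx2, Hey1, Nog and Dlx5 had SEs of 0.139 to 0.188, against a median of 0.0815 over all genes. Falls of these genes were therefore harder to call than that rate implies. Counted afterwards, at an unadjusted p under 0.05 limma gave 5 lower and 0 higher, 7 of the 10 differences were negative, and the median was -0.19. A smaller fall of BMP output than the prediction asked for was not tested on other genes. Atoh8, which fell, and Smad7, which differed by 0.12 ± 0.07 (SE) and did not pass, are also BMP targets. Their values had been seen, so they were not among the 10.

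The rise of interferon-stimulated genes in shARF cells was weighed against other origins. Macrophages or lymphocytes in the shARF cultures would bring their own transcripts. The 10 measured markers, however, had a median difference of 0.0772 (SD 0.291) against 1.00 for the interferon list. Of the 10, Cd53 was called higher, by 0.66, a call lost on leaving out any 1 of the 6 arrays. Lyz2, Ptprc and Csf1r lay below the detection level on all 6 arrays. Each replicate number occurs once in each group, so the differences within numbers 1, 2 and 3, with medians of 1.15, 0.952 and 1.02, restate the rise and decide nothing about variation that goes with the number. A response to the ARF hairpin itself, and not to lower ARF, cannot be told apart from an effect of ARF, because 1 ARF hairpin construct is named in the labels. An interferon response that follows from lower ARF is therefore a hypothesis that these data leave open.

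The number of changed genes, 607, was compared with other splits of the 6 arrays into 3 and 3. There are 10 splits, too few for a share under 0.05; 1 of the 10, the real one, gave 607 genes in limma, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 3361 genes and the others 347 to 823. Every other split puts arrays of both groups on each side, so a group difference adds to the spread within the sides. Low counts in those splits can follow from that alone, so the comparison does not decide whether the 607 arose by chance. Gain or loss of a whole chromosome in one set of cultures would shift the genes of that chromosome together. The medians of the 20 chromosomes with at least 20 tested genes lay between -0.03 and 0.01, the farthest from 0 by 0.028 on the log2 scale, which argues against it as a source of the changes.

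The fall of 7 contractile and TGF-beta genes was weighed in the same way. A lower share of fibroblasts in the shARF cultures would lower the fibroblast markers by about as much as these 7 genes, whose median was -0.53, a size that choosing them by their calls can overstate. The markers, with a median of -0.0754 (SD 0.197), lay above that by more than their SD. The whole list of 20 genes had a median of -0.082, near that of the markers, so part of the gap comes from choosing the 7. The values argue against such a share only as the source of falls as large as those of the 7 genes. A difference in proliferation would shift the members of the 2 cell cycle lists together. Their medians were -0.0401 (G1/S) and -0.003 (G2/M), and 10 and 12 of 25 differences were positive. The differences ran from -0.172 to 0.15 and from -0.121 to 0.151, and 0 passed limma's test or SAM. These values argue against a proliferation difference large enough to shift these lists together, and leave a smaller one open. Actin and myosin genes are also sensitive to culture density and stiffness, for which the labels give no values, so this stays untested. An effect of lower ARF on these genes was not tested apart from these explanations.

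The replicate 2 arrays stood above the other arrays of their group in the interferon list, by a median of 0.33 in shSCR and 0.22 in shARF on the log2 scale. If replicate numbers carry no meaning, the same number is highest in both groups with a chance of 33.3%. Further tests of this pattern were run and left out after their results were seen, so its origin is not weighed here.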
